A study of Mus musculus with 6 samples.

How the data were processed

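RNA sequencing had been carried out on 6 libraries of cultured wild-type mouse alveolar macrophages taken at day 2. The libraries formed 3 groups of 2: without GM-CSF (granulocyte-macrophage colony-stimulating factor), with GM-CSF, and with GM-CSF and a treatment that the labels name only DON. Groups and replicate numbers were taken from the sample titles and treatment labels. The labels do not say whether the 2 replicates of a group were separate cultures or came from separate animals. They also name a cell line, AM, without saying whether the cells were primary or an established line.

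The deposited count table held whole-number counts for 16840 gene symbols in all 6 libraries, with no column left out of use. The lowest total of a gene over the 6 libraries was 2. A second deposited table held FPKM values made by the authors for the same genes, with the same 10753 zero values. The gene length implied by dividing counts by FPKM was taken relative to its mean over libraries and to each library's median. Its SD over the 6 libraries was over 1% for 2146 of 4288 genes with at least 1000 counts (50.0%), and over 5% for 516 (12.0%). This leaves open whether the counts were rounded estimates. The authors' processing notes list STAR 2.6.0a, featureCounts, Subread 1.4.6, DESeq2 1.28.1 and the mouse genome build mm10 (GRCm38), without saying what each did. The gene annotation, the strand setting and any filter on genes are not given in the sources used here.

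Total counts per library were between 28321986 and 35196387. Where a group had no counts of a gene, a floor of 3 counts per library was used, which was 0.0907 CPM, counts scaled to a common library size, in the group without GM-CSF. Floors and counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates were compared with a chi-square statistic over genes, which was 8.90 per degree of freedom without GM-CSF, 5.54 with GM-CSF and 4.67 with GM-CSF and DON. No replicate pair was a copy of the same column.

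Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, with Python 3.11.15 for tables and figures. Genes with low counts were removed with filterByExpr (minimum count 10), which left 12340. Libraries were scaled by the trimmed mean of M values (TMM). A single model with 1 coefficient per group was fitted to all 6 libraries, and each comparison was a two-sided contrast in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested. A gene was called changed at an adjusted p under 0.05. The fit had 3 residual degrees of freedom and 6.74 prior degrees of freedom, and the common biological coefficient of variation was 0.0501. Mean CPM values are given with the SD over 2 libraries, and log2 fold changes with their SE. CPM values of genes were taken with TMM-scaled library sizes. The principal components and the correlations of replicate differences used log2 CPM from unscaled total counts, over genes with a mean of at least 10 CPM.

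The comparisons were GM-CSF against no GM-CSF, GM-CSF with DON against GM-CSF, and GM-CSF with DON against no GM-CSF. Before the data were examined, 27 gene lists were fixed from general knowledge, 5 of them markers of cells other than macrophages. They held 764 entries, of which 726 were found in the table, 5 of these by an older symbol. Among the 692 distinct genes found in the table, 34 were in more than 1 list. Lists were tested with limma's camera on voom-weighted log2 CPM with a preset inter-gene correlation of 0.01, adjusted over the 27 lists of a comparison. The test was repeated with the correlation estimated from the data, where it had only 3 degrees of freedom. It was also repeated with fry, which tests whether the genes of a list move and does not compare them with other genes. Members of each list were counted as higher or lower after adjustment over all genes, and again adjusted over the list alone.

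Genes named in the text were chosen by a rule fixed before the data were examined. For the first comparisons, against no GM-CSF and against GM-CSF, the rule took the 10 genes with the largest rise and the 10 with the largest fall among genes called changed. They also needed a mean of at least 10 CPM, no overlap between the libraries of both groups and a symbol that was not a predicted model or pseudogene. For the third comparison it took 5 in each direction. It also took up to 4 members of each list with the smallest adjusted p, and a fixed set of genes in every comparison, among them Csf2ra, Csf2rb, Pparg, Myc, Mki67, Asns and Siglec5. Genes named outside the rule are identified as such.

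The relation between the GM-CSF and DON effects was counted over genes and set beside 20 simulations with no effect in which the GM-CSF libraries were shared by both contrasts. For the genes changed at least 2-fold by GM-CSF, 20 further simulations gave the libraries with both GM-CSF and DON the means of the group without GM-CSF. The tests were checked on simulated counts in which 200 of 12340 genes changed by 1.5-, 2- or 4-fold, with 1 simulation per comparison. For GM-CSF against no GM-CSF, edgeR's test recovered 77.6% of the 1.5-fold changes, 85.1% of the 2-fold changes and 93.9% of the 4-fold changes. False calls were 14.9% of its calls in that comparison, 9.57% for DON against GM-CSF and 8.02% for GM-CSF with DON against no GM-CSF, all above the nominal 5%. DESeq2's Wald test gave 6.98%, 5.71% and 4.62% false calls on the same counts. Such shares depend on how many genes truly change. They do not carry over to the data, where 56.8% of genes were called for GM-CSF against no GM-CSF. In each of the 3 simulations camera called a changed list of 30 genes and 0 of 26 random lists. With an estimated correlation camera also called the changed list (adjusted p of 0.00357, 0.0051 and 0.00227) and 0 random lists. Genes were drawn independently and random lists held no changed gene, so calls on lists of correlated genes were not checked. In the data the estimated correlation was 0.597 for mitosis and 0.492 for cholesterol synthesis with GM-CSF against none, and -0.00484 for interferon response.

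The alternatives were DESeq2 size factors and upper quartile scaling in edgeR, and DESeq2 1.42.0 with its Wald test. No filter, a filter of 1 CPM in 2 libraries, a minimum fold change of 2 and a fit of only the 4 libraries compared were also tried. Further alternatives were limma on log2(FPKM + 1) and log2(FPKM + 0.1), the first also without the filter of 1 FPKM in 2 libraries, the replicate number as a block, and each library left out in turn. When a group was left with 1 library, the pooled spread of the other groups was taken to hold for it. For locations, the coordinates of genes were taken from the GENCODE annotation of GRCm38. Of the 16840 symbols, 14206 were current RefSeq symbols, 1668 were matched through older names and 966 were not matched, and the table's own symbols are printed.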

Results

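The transcriptomes of mouse alveolar macrophages, the resident macrophages of the air spaces of the lung, were measured by RNA sequencing after culture, at day 2. The labels do not say whether the cells were primary or an established line. There were 3 groups of 2 libraries each: no GM-CSF, GM-CSF, and GM-CSF with DON. GM-CSF is the cytokine on which the development and upkeep of these cells depend. DON is given by the labels without its full name. Total counts were 34407582 and 35196387 without GM-CSF, 33005846 and 28800939 with GM-CSF, and 28321986 and 31782295 with GM-CSF and DON. A count was present for between 14892 and 15188 genes per library, and 12340 genes were tested. The median SE of a log2 fold change was 0.08 in each comparison. The labels do not say that replicates were separate cultures or animals, so p-values measure only the spread between these samples. Values are CPM as mean ± SD (n = 2) or log2 fold changes ± SE, and a gene is said to have risen or fallen only where its adjusted p was under 0.05.

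The 3 groups separated from each other, with the replicates of each group close together. On the 1000 most variable genes the first principal component held 70.2% of the variance and set the libraries without GM-CSF apart from the others. The second held 28.4% and set the libraries with DON apart from those with GM-CSF alone. The 12 mitochondrially encoded genes took 3.21 ± 0.0936% of counts without GM-CSF, 2.42 ± 0.282% with GM-CSF and 2.54 ± 0.0863% with DON (SD, n = 2). Ribosomal protein genes took 2.47 ± 0.05%, 3.03 ± 0.064% and 3.01 ± 0.088%. The 10 most abundant genes took 15.2 ± 0.135% of counts without GM-CSF, 11.9 ± 0.112% with it and 14.2 ± 0.296% with DON.

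**Figure D1:**
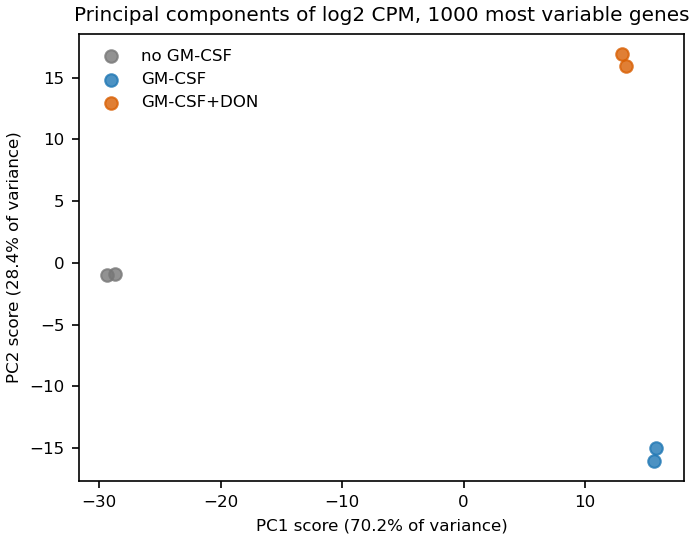
Scores of the 6 libraries on the first and second principal components of log2 CPM over 1000 genes, with 1 point per library coloured by group. The libraries without GM-CSF lie at -29.4 and -28.7 on the first component, and the GM-CSF and GM-CSF+DON libraries lie on opposite sides of 0 on the second.

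The first comparison asked what GM-CSF did to the cells. Carbonic anhydrase 4 (Car4), a marker of mature alveolar macrophages, rose from 0.226 ± 0.0159 to 656 ± 6.51 CPM, a log2 fold change of 11.48 ± 0.09. The chemokine gene Ccl17 rose from 0.439 ± 0.032 to 1246 ± 38.5 CPM (11.46 ± 0.09). The cytokine signalling inhibitors Cish and Socs3, targets of the STAT pathway, rose from 0.834 ± 0.213 to 139 ± 2.27 CPM and from 2.85 ± 0.209 to 94.8 ± 4.34 CPM. In the other direction, Fyb, an adaptor protein gene, fell from 23.9 ± 1.02 to 0.201 ± 0.0473 CPM, a log2 fold change of -6.85 ± 0.24. Trem2, a lipid-sensing receptor of tissue macrophages, fell from 568 ± 12.6 to 83.1 ± 2.29 CPM (-2.78 ± 0.04).

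Of 12340 genes, 7014 changed with GM-CSF in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3393 up and 3621 down. Changes of at least 2-fold were found for 1446 genes, 623 up and 823 down. Among genes with a mean of at least 10 CPM over the libraries compared, the other largest rises were of Ear6 (log2 fold change 6.75 ± 0.16), the chemokine Ccl2 (5.61 ± 0.14), the activin subunit Inhba (5.34 ± 0.18), Nov (from 1.10 ± 0.166 to 35.5 ± 2.56 CPM) and Ece1 (4.84 ± 0.16). Ear11, an eosinophil-associated ribonuclease, had no counts in either library without GM-CSF and 21.2 ± 3.28 CPM with it. It was at least 233-fold higher against a floor of 3 counts per library. Ear6 and Ear11 belong to a multigene family of similar sequence, so reads may be shared between members. Among the same genes, the largest falls after Fyb were of Cd300lh (-5.34 ± 0.19), Irg1, which makes itaconate (-4.91 ± 0.15), Treml4 (-4.74 ± 0.13), the chemokine receptor Cxcr2 (-4.53 ± 0.09) and the membrane protease Mmp14 (-4.20 ± 0.13). Then came Lpcat2 (-3.97 ± 0.11), H2-M2 (-3.91 ± 0.16), Neurl3 (-3.68 ± 0.09) and the kinase Ikbke (-3.50 ± 0.09). Adjusted p for the 20 genes lay between 5.11e-13 and 2.16e-08. Without GM-CSF replicate 2 the log2 fold change of Cd300lh was -6.04.

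In GRCm38 coordinates, Car4 lies on chromosome 11 from 84957786 to 84966044 and Ccl17 on chromosome 8 from 94810453 to 94812036. Cish lies on chromosome 9 from 107296026 to 107302784, Fyb on chromosome 15 from 6522853 to 6663313, and Trem2 on chromosome 17 from 48346401 to 48354147. All are annotated as protein-coding genes, and counts were summed over each gene.

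Genes of cell division rose together. Of 40 mitosis genes, 40 rose with GM-CSF, and 40 when adjusted over the list alone, with a median log2 fold change of 1.26 (2.39-fold). Cyclin B1 (Ccnb1) went from 37.3 ± 1.47 to 114 ± 0.336 CPM, Kif20a from 34.4 ± 0.619 to 89.0 ± 4.36, and Ube2c from 34.2 ± 2.10 to 103 ± 7.29. Mki67 rose by 1.12 ± 0.18 on the log2 scale. The camera test of the list gave adjusted p = 1.83e-19, and adjusted p = 0.285 with an estimated correlation. Of 40 genes of DNA replication and the G1/S step, 33 rose and 1 fell (34 and 1 adjusted over the list alone), with the ribonucleotide reductase subunits Rrm2 (1.01 ± 0.06) and Rrm1 (0.86 ± 0.06) as examples. The list median was 0.42, with camera adjusted p = 2.13e-08 and adjusted p = 0.361 with an estimated correlation.

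Of 39 tested genes of the ATF4 amino acid response, 33 rose and 1 fell, the same numbers adjusted over the list alone, with a median of 0.87 (1.83-fold). Phgdh, the first enzyme of serine synthesis, rose from 42.4 ± 1.58 to 245 ± 5.12 CPM, asparagine synthetase (Asns) from 22.7 ± 2.31 to 103 ± 5.94, and the amino acid transporter Slc7a5 from 31.3 ± 4.22 to 151 ± 1.27. The adjusted p was 5.97e-13 by camera, and 0.285 with an estimated correlation. Of 25 genes of the unfolded protein response, 22 rose and 2 fell (22 and 3 adjusted over the list alone), led by the chaperone gene Pdia4 (2.16 ± 0.05). Camera gave adjusted p = 1.48e-08, and adjusted p = 0.285 with an estimated correlation.

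Among 63 genes of the TCA cycle and oxidative phosphorylation, all encoded in the nucleus, 49 rose and 1 fell (50 and 1 adjusted over the list alone), with a median of 0.41. Atp5b, a subunit of ATP synthase, rose from 701 ± 11.9 to 1209 ± 19.3 CPM, and Mdh2 from 175 ± 5.12 to 280 ± 7.79. Camera gave adjusted p = 6.11e-13, and adjusted p = 0.312 with an estimated correlation, while the share of mitochondrially encoded counts was 3.21% without GM-CSF and 2.42% with it. Of 32 genes of MYC and ribosome biogenesis, 23 rose and 0 fell, also when adjusted over the list alone, among them the polyamine enzymes Srm (0.99 ± 0.06) and Odc1 (0.97 ± 0.07). The list's adjusted p was 1.16e-06 by camera and 0.285 with an estimated correlation, and ribosomal protein genes took 2.47% of counts without GM-CSF and 3.03% with it. Myc itself was at 65.5 ± 3.80 and 72.0 ± 3.54 CPM, with an adjusted p of 0.0734. It passed the test without no GM-CSF replicate 2 (0.20, adjusted p = 0.0298). Of 32 genes of purine and pyrimidine synthesis, 21 rose and 3 fell, also adjusted over the list alone, with Shmt2 (1.46 ± 0.06) and Mthfd2 (1.10 ± 0.08) as examples. Camera's adjusted p was 7.94e-05, and 0.285 with an estimated correlation. Of 24 glutamine enzymes and transporters, 15 rose and 3 fell, also adjusted over the list alone. Slc38a2 rose by 0.79 ± 0.05, and glutamine synthetase (Glul) fell from 301 ± 1.10 to 114 ± 1.10 CPM. Camera's adjusted p for the list was 0.00209, and 0.285 with an estimated correlation.

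Of 25 cholesterol synthesis genes, 22 fell and 1 rose (22 and 2 adjusted over the list alone), with a median of -1.15. Insig1 fell from 361 ± 28.1 to 86.0 ± 5.03 CPM, Sc4mol from 164 ± 11.2 to 38.8 ± 0.742 and Sc5d from 53.2 ± 3.71 to 12.1 ± 0.843. The camera adjusted p was 9.14e-09, and 0.322 with an estimated correlation. Of 32 genes of fatty acid oxidation and lipid storage, 19 fell and 3 rose, also adjusted over the list alone, among them the lysosomal lipase Lipa (-0.92 ± 0.03) and the fatty acid binding protein Fabp4 (-1.14 ± 0.06). Camera gave adjusted p = 0.000567, and adjusted p = 0.285 with an estimated correlation. Of 25 genes of NRF2 and oxidative stress, 22 fell and 2 rose, also adjusted over the list alone, with a median of -0.67. Gstm1 fell from 1183 ± 22.9 to 354 ± 0.329 CPM, and the ferritin chains Fth1 and Ftl1 fell by 0.94 ± 0.04 and 0.74 ± 0.03 on the log2 scale. Camera's adjusted p was 1.83e-08, and 0.285 with an estimated correlation.

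Among 21 markers of interstitial and monocyte-derived macrophages, 15 fell and 3 rose, also adjusted over the list alone, with a median of -1.14. Besides Trem2 and Mmp14, the selenoprotein gene Sepp1 fell (-1.52 ± 0.05). Camera gave adjusted p = 0.000251, and adjusted p = 0.285 with an estimated correlation. Of 25 interferon response genes, 14 fell and 3 rose (17 and 3 adjusted over the list alone), with Ddx58 (-1.04 ± 0.08), Gbp2 (-0.93 ± 0.07) and Stat2 (-0.53 ± 0.05) as examples. Camera's adjusted p was 0.00409, and 0.285 with an estimated correlation. Of 29 immediate early and MAPK feedback genes, 16 rose and 8 fell (18 and 9 adjusted over the list alone). Klf4 (1.52 ± 0.05) and Dusp1 (1.67 ± 0.09) rose, while Junb (-0.92 ± 0.04) and the ERK phosphatase Dusp6 (-1.42 ± 0.07) fell, with camera adjusted p = 0.0417 and adjusted p = 0.361 with an estimated correlation.

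Some lists moved in both directions and did not pass the camera test. Of 37 alveolar macrophage identity genes, 15 rose and 15 fell, also adjusted over the list alone, with adjusted p = 0.758. Here Car4, Slc39a2 (3.04 ± 0.05), 1600029D21Rik (the marker Plet1, 2.80 ± 0.05) and Chi3l3 (1.61 ± 0.03) rose, while the master regulator Pparg (-0.34 ± 0.05) and Siglec5 (-0.33 ± 0.05) fell. The list's median was -0.05, but its mean was 0.59 and the test pointed up. Of 26 GM-CSF receptor and STAT5 target genes, 12 rose and 8 fell, also adjusted over the list alone (adjusted p = 0.258), with Socs2 up by 3.56 ± 0.08. The receptor chain Csf2ra fell by 0.39 ± 0.04 on the log2 scale, and Csf2rb was at 1140 ± 8.27 and 1123 ± 47.2 CPM (adjusted p = 0.668). Of 25 NF-kB inflammatory genes, 7 rose and 14 fell, also adjusted over the list alone (adjusted p = 0.109). The chemokines Ccl3 (3.66 ± 0.05) and Ccl4 (4.38 ± 0.12) rose and Relb fell (-1.46 ± 0.06), and the list's median was -0.23 while its mean was 0.18.

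Of 24 glycolysis genes, 8 rose and 10 fell (8 and 11 adjusted over the list alone), with adjusted p = 0.886. Eno1 rose from 491 ± 3.74 to 1077 ± 15.2 CPM and Pfkp from 67.2 ± 0.114 to 213 ± 5.91, and Pfkfb4 fell by 1.31 ± 0.06 on the log2 scale. The median was -0.04 and the test pointed up. Of 20 genes of fatty acid synthesis and LXR targets, 5 rose and 8 fell, also adjusted over the list alone (adjusted p = 0.44), with Elovl6 up (2.27 ± 0.12) and the LXR alpha gene Nr1h3 down (-1.80 ± 0.09). Of 15 genes of MHC class II presentation, 6 rose and 6 fell, also adjusted over the list alone (adjusted p = 0.758), with H2-DMa (1.71 ± 0.05) and Cd80 (1.43 ± 0.12) up. Their median was -0.18, their mean 0.08 and the test pointed up. Of 24 p53 targets, 9 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.33), with Cdkn1a up (1.66 ± 0.07) and Phlda3 down (-1.73 ± 0.06). Of 19 genes of alternative activation and repair, 9 rose and 6 fell (10 and 7 adjusted over the list alone), with adjusted p = 0.374, Il4ra up (1.62 ± 0.06) and Gpnmb down (-1.70 ± 0.03).

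Markers of other cell types were mostly low. Of 5 dendritic cell markers tested, 3 rose and 0 fell, also adjusted over the list alone: Zbtb46 from 0.877 ± 0.0213 to 8.25 ± 0.297 CPM, Batf3 from 2.77 ± 0.644 to 10.1 ± 0.084 and Clec9a from 4.43 ± 0.128 to 8.50 ± 0.0556. Camera's adjusted p was 0.0417, and 0.285 with an estimated correlation. Of 4 granulocyte and mast cell markers, 3 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.112). Cxcr2, Csf3r (-4.76) and S100a8 fell, the last from 16.6 ± 0.901 to 4.05 ± 0.412 CPM, and Mmp8 rose by 1.39 ± 0.06. Of 9 lung epithelium markers, 3 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.565), and the riser was Cdh1, from 13.8 ± 3.33 to 98.0 ± 3.62 CPM. The fallers were Abca3 (-0.42), Scgb1a1 (-3.05, with 0 and 8 counts in the GM-CSF libraries, and -1.98 without the library at 0) and Epcam (-1.45), the last not called without no GM-CSF replicate 2 (adjusted p = 0.0589) or without GM-CSF replicate 1 (adjusted p = 0.0759). Of 4 lymphocyte markers, 1 fell and 0 rose (adjusted p = 0.565), also adjusted over the list alone, and Cd2 was at 193 ± 0.771 and 195 ± 4.86 CPM. The faller was Cd4, with 30 counts without GM-CSF and 1 count with it. Of 4 markers of stroma and endothelium, 1 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.589). It was Cdh5, with 3 counts without GM-CSF and 90 with it, a ratio of 31.1 with a counting interval of 10.3 to 154.

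**Figure D2:**
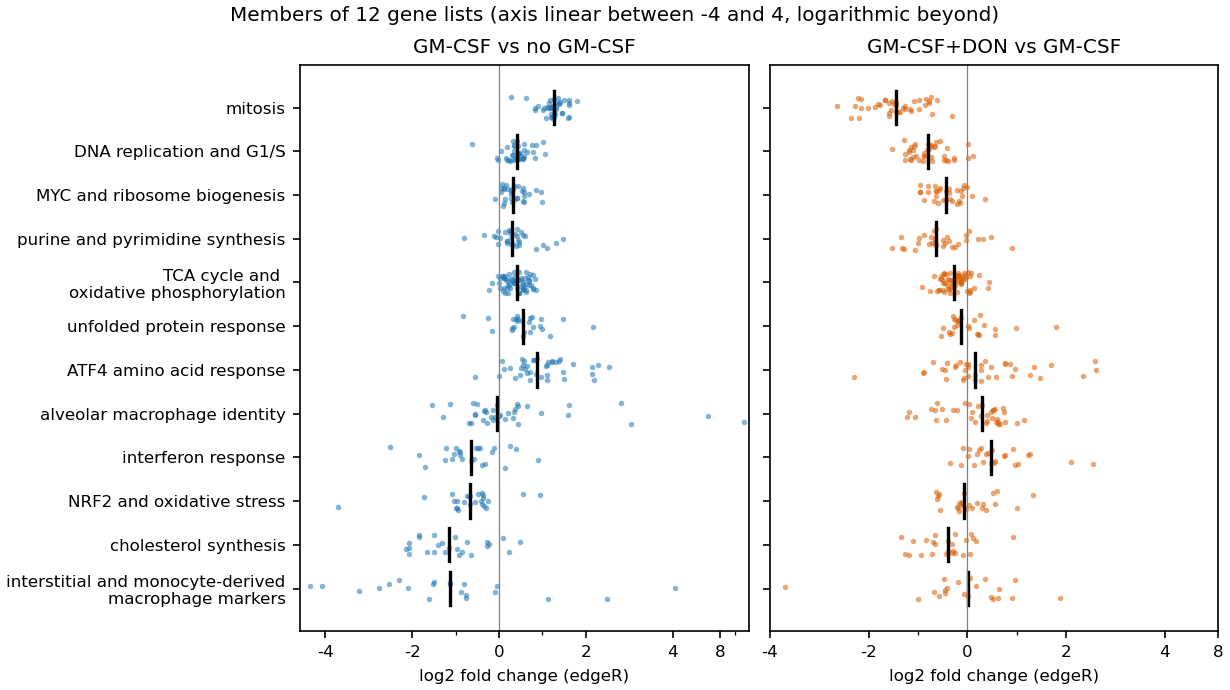
Log2 fold changes of the tested members of 12 gene lists, with 1 point per gene and a black line at each list's median, for GM-CSF against no GM-CSF on the left and for DON on the right. The axis is linear between -4 and 4 and logarithmic beyond, and 1 interstitial marker with no counts with DON is drawn at its fitted value, which is no bound. The mitosis medians lie at 1.26 and -1.45, and those of cholesterol synthesis at -1.15 and -0.40.

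The comparison of GM-CSF with DON against GM-CSF alone asked what DON did to cells that had the cytokine. The stress genes Gadd45a, Ddit3 and Trib3 rose, the last from 20.1 ± 2.76 to 102 ± 2.30 CPM. Ddit3, the transcription factor CHOP of the integrated stress response, went from 20.6 ± 0.811 to 124 ± 0.642 CPM, and its level without GM-CSF was 20.6 ± 2.90. The chemokine Ccl2, which had risen with GM-CSF, fell from 69.6 ± 9.45 to 6.91 ± 0.656 CPM, a log2 fold change of -3.33 ± 0.11. All 40 mitosis genes fell, with a median of -1.45 (2.72-fold lower). The fatty acid desaturase Scd2 fell from 302 ± 48.6 to 51.2 ± 0.452 CPM.

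With DON 7111 genes changed in edgeR's test, 3555 up and 3556 down. Changes of at least 2-fold numbered 1156, 632 up and 524 down. Among genes with a mean of at least 10 CPM, the 10 largest rises were of Gadd45a (2.80 ± 0.10), Ddit3 (2.59 ± 0.08), the glutathione-degrading enzyme Chac1 (2.58 ± 0.12), the chemokine receptor Cxcr1 (2.57 ± 0.05), Tcp11l2 (2.55 ± 0.09), Tmem140 (2.48 ± 0.07), Trib3 (2.34 ± 0.08), the ubiquitin ligase Fbxo32 (2.23 ± 0.12), N4bp2l1 (2.18 ± 0.07) and Arhgef3 (2.18 ± 0.05). After Ccl2, the largest falls were of Ccl4 (-2.98 ± 0.10), the cell cycle genes Cdkn3 (-2.97 ± 0.11) and Cdc20 (-2.63 ± 0.10), and Adam8 (-2.60 ± 0.13). Scd2 (-2.56 ± 0.10), Gpr35 (-2.45 ± 0.14), the mitotic kinase Aurka (-2.35 ± 0.09), the transcription factor Irf4 (-2.27 ± 0.08) and Id1 (-2.25 ± 0.11) followed. The adjusted p of these 20 genes lay between 5.38e-09 and 5.23e-07. Of the larger ones, Ccl2 lies on chromosome 11 from 82035571 to 82037453, Chac1 on chromosome 2 from 119351229 to 119354381, Trib3 on chromosome 2 from 152337422 to 152344032 and Scd2 on chromosome 19 from 44293674 to 44306864 (GRCm38).

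Of 40 mitosis genes, 40 fell when adjusted over all genes or over the list alone. Plk1 went from 74.7 ± 1.73 to 16.8 ± 0.43 CPM, Kif20a to 19.5 ± 0.27 and Ccnb1 to 28.4 ± 2.17, with camera adjusted p = 6.28e-20 and adjusted p = 0.312 with an estimated correlation. Mki67 fell by 1.36 ± 0.18 on the log2 scale. Of 40 genes of DNA replication and the G1/S step, 36 fell and 0 rose (37 and 0 adjusted over the list alone), with a median of -0.80 and Mcm6 (-1.16 ± 0.05) and Mcm5 (-1.26 ± 0.07) as examples. Camera gave adjusted p = 2.54e-13, and adjusted p = 0.312 with an estimated correlation. Of 32 purine and pyrimidine synthesis genes, 24 fell and 4 rose (25 and 4 adjusted over the list alone), among them Rrm1 (-1.28 ± 0.06) and Atic (-0.73 ± 0.05), with camera adjusted p = 6.23e-06 and adjusted p = 0.312 with an estimated correlation. Of 32 genes of MYC and ribosome biogenesis, 23 fell and 1 rose (24 and 1 adjusted over the list alone). Nop58 (-0.97 ± 0.06), Nolc1 (-0.95 ± 0.05) and Myc itself (-0.58 ± 0.06) fell, with camera adjusted p = 1.74e-06 and adjusted p = 0.312 with an estimated correlation. Ribosomal protein genes took 3.03% of counts with GM-CSF and 3.01% with DON.

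Of 63 genes of the TCA cycle and oxidative phosphorylation, 41 fell and 3 rose (42 and 3 adjusted over the list alone), with a median of -0.26. Citrate synthase (Cs) fell from 360 ± 5.48 to 226 ± 5.66 CPM and Cycs from 114 ± 0.452 to 60.8 ± 1.61. Camera's adjusted p was 6.27e-07, and 0.473 with an estimated correlation, while the mitochondrially encoded share was 2.42% and 2.54%. Of 24 glycolysis genes, 14 fell and 3 rose, also adjusted over the list alone, with Eno1 (-0.91 ± 0.04), Pgk1 (-0.86 ± 0.04) and the lactate exporter Slc16a3 (-1.62 ± 0.08) among them. Here camera gave adjusted p = 0.00262, and adjusted p = 0.312 with an estimated correlation. Of 25 cholesterol synthesis genes, 18 fell and 1 rose, also adjusted over the list alone, with a median of -0.40. The isomerase gene Idi1 fell from 43.8 ± 0.263 to 19.4 ± 1.32 CPM, and the list had camera adjusted p = 0.000754 and adjusted p = 0.547 with an estimated correlation. Of 20 genes of fatty acid synthesis and LXR targets, 10 fell and 3 rose, also adjusted over the list alone. Scd2, Acsl3 (-1.37 ± 0.10) and Fads1 (-0.84 ± 0.06) fell, with camera adjusted p = 0.0107 and adjusted p = 0.473 with an estimated correlation.

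Of 26 GM-CSF receptor and STAT5 targets, 15 fell and 5 rose, also adjusted over the list alone. Socs3 fell from 94.8 ± 4.34 to 21.8 ± 1.97 CPM, Irf4 from 76.9 ± 5.76 to 15.9 ± 1.25 and Ccnd2 from 189 ± 15.6 to 87.0 ± 4.94, while the receptor chain Csf2ra rose (0.47 ± 0.04) and Csf2rb had an adjusted p of 0.298 (0.0224 under upper quartile scaling). The list's adjusted p was 0.00984 by camera and 0.312 with an estimated correlation. Of 25 NF-kB inflammatory genes, 15 fell and 5 rose, also adjusted over the list alone, with Ccl2, Ccl4, Ccl3 (-1.30 ± 0.05) and Tnf (-2.18 ± 0.09) among the fallers. The adjusted p was 0.0203 by camera and 0.312 with an estimated correlation. Of 29 immediate early and MAPK feedback genes, 20 fell and 3 rose, also adjusted over the list alone, including Dusp5 (-1.70 ± 0.08), Fos (-1.49 ± 0.11) and Zfp36 (-1.04 ± 0.07). Their adjusted p was 0.000754 by camera and 0.312 with an estimated correlation. Of 19 genes of alternative activation and repair, 14 fell and 4 rose, also adjusted over the list alone. Il1rn (-1.59 ± 0.05) and Tgm2 (-1.20 ± 0.06) fell and Gpnmb rose (0.97 ± 0.03), with camera adjusted p = 0.0114 and adjusted p = 0.312 with an estimated correlation.

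Of the lists fixed for testing, 3 passed the camera test with DON and pointed up. Of 39 genes of the ATF4 amino acid response, 20 rose and 9 fell (20 and 10 adjusted over the list alone), with a median of 0.16. Besides Ddit3 and Trib3, the amino acid transporter chain Slc3a2 rose from 230 ± 3.06 to 588 ± 26.4 CPM and Sesn2 from 36.7 ± 3.33 to 118 ± 1.31, while Asns was at 103 ± 5.94 and 99.2 ± 2.43 CPM (adjusted p = 0.544). The camera test gave adjusted p = 0.0203, and adjusted p = 0.547 with an estimated correlation. Of 37 alveolar macrophage identity genes, 20 rose and 11 fell (22 and 11 adjusted over the list alone). Slc39a2 (1.14 ± 0.05), Atp6v0d2 (0.55 ± 0.04), Pparg (0.40 ± 0.05) and Siglec5 (0.27 ± 0.05) rose, and Car4 fell from 656 ± 6.51 to 314 ± 15.7 CPM. The list's adjusted p was 0.0338 by camera and 0.453 with an estimated correlation. Of 25 interferon response genes, 10 rose and 0 fell, also adjusted over the list alone, with Gbp2 going from 19.7 ± 0.957 to 84.5 ± 0.977 CPM and Stat2 and Irf1 up by 0.77 ± 0.05 and 0.75 ± 0.05. By camera the adjusted p was 0.00984, and 0.312 with an estimated correlation.

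The other lists did not pass the camera test with DON. Of 24 glutamine enzymes and transporters, 3 rose and 11 fell, also adjusted over the list alone (adjusted p = 0.127), among them Psat1 (-0.88 ± 0.05), Slc38a1 (-0.62 ± 0.05) and the riser Slc38a7 (0.80 ± 0.06). Of 32 genes of fatty acid oxidation and lipid storage, 13 rose and 7 fell, also adjusted over the list alone (adjusted p = 0.426), with the lipase gene Pnpla2 up by 1.09 ± 0.05 and Cd36 by 0.67 ± 0.05. Of 25 unfolded protein response genes, 9 rose and 13 fell (10 and 13 adjusted over the list alone), with adjusted p = 0.935, Ppp1r15a up (1.80 ± 0.09) and Dnajb11 down (-0.54 ± 0.06). Their median was -0.12 and the camera test pointed down, while the mean was 0.06. Of 25 genes of NRF2 and oxidative stress, 9 rose and 8 fell, also adjusted over the list alone (adjusted p = 0.956), with Gstm1 (1.33 ± 0.04) and Fth1 (0.60 ± 0.04) up and Txnrd1 (-0.63 ± 0.05) down. The median was -0.07 (0.00 under upper quartile scaling), while the mean was 0.05 and the test pointed up.

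Of 24 p53 targets, 9 rose and 6 fell, also adjusted over the list alone (adjusted p = 0.36), with Bbc3 up by 2.13 ± 0.09. Of 15 genes of MHC class II presentation, 5 rose and 7 fell (6 and 7 adjusted over the list alone), with adjusted p = 0.973. Cd74 (0.80 ± 0.04) and H2-Aa (0.57 ± 0.05) rose and H2-DMa (-0.80 ± 0.05) fell, and the median was 0.08 while the mean was -0.06 and the test pointed down. Of 21 interstitial and monocyte-derived macrophage markers, 7 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.414), with Trem2 (0.90 ± 0.04) and Mertk (0.64 ± 0.06) up. The median was 0.02, the mean -0.07, and the test pointed up. Of 5 dendritic cell markers, 1 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.757): Clec9a rose by 0.86 ± 0.10, and Batf3 and Zbtb46 fell by 0.91 ± 0.14 and 1.17 ± 0.18. Of 9 lung epithelium markers, 1 rose and 2 fell (1 and 1 adjusted over the list alone), with adjusted p = 0.425, and Cdh1 fell to 25.6 ± 0.705 CPM. The riser Abca3 (0.22) was not called without GM-CSF replicate 1 (adjusted p = 0.0676) or DON replicate 2 (0.0664), and the faller Cldn18 (-1.61) was not called without either no GM-CSF library, either GM-CSF library or DON replicate 2 (adjusted p up to 0.254) or under upper quartile scaling (0.0521), with -2.47 without DON replicate 1 and -1.02 without DON replicate 2. Of 4 granulocyte and mast cell markers, 2 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.36), with Cxcr2 up by 1.69 ± 0.10 to 8.40 ± 0.584 CPM. The other riser, Csf3r (0.76), was not called without GM-CSF replicate 1 or 2 or without DON replicate 1, with adjusted p of 0.0688, 0.125 and 0.225. Of 4 lymphocyte markers, 0 rose and 0 fell in edgeR's test, also adjusted over the list alone, and 0 had an unadjusted p under 0.05 (list adjusted p = 0.973). Of these, Cd2 was at 184 ± 5.70 CPM. Their median and mean were 0.02 and 0.18, and the test pointed down. Of 4 markers of stroma and endothelium, 1 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.973), with a median of -0.22 and a mean of 0.09. The riser Pdgfra (1.90) was not called without GM-CSF replicate 2 or DON replicate 1 (adjusted p of 0.137 and 0.101) and was 3.32 without GM-CSF replicate 1, and the faller Cdh5 (-1.08) was not called without GM-CSF replicate 1, GM-CSF replicate 2 or DON replicate 1 (0.0637, 0.130 and 0.137).

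**Figure D3:**
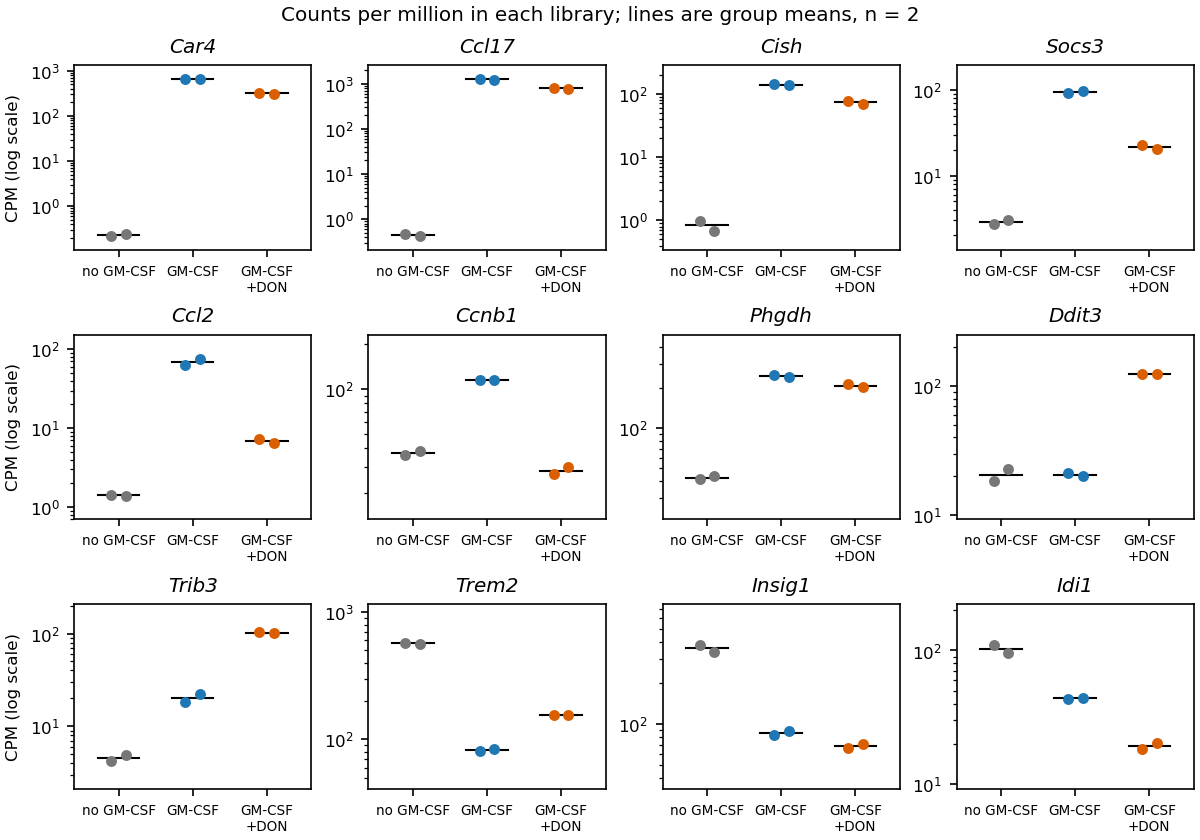
CPM on a log axis of 12 genes, with 1 point per library and a line at each group's mean (n = 2). Car4, Ccl17, Cish, Socs3 and Ccl2 are lowest without GM-CSF, Ddit3 and Trib3 are highest with DON at 124 and 102 CPM, and Idi1 is at 43.8 CPM with GM-CSF and 19.4 with DON.

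Many changes with DON ran against those with GM-CSF. Of 3393 genes that rose with GM-CSF, 2036 (60.0%) fell with DON, 377 (11.1%) rose further and 980 (28.9%) did not pass. Of 3621 that fell with GM-CSF, 1877 (51.8%) rose with DON, 558 (15.4%) fell further and 1186 (32.8%) did not pass. Among all 7014 genes changed with GM-CSF, 55.8% thus changed in the opposite direction with DON, and with a minimum fold change of 2 the share was 29.1%. Independent lists of these sizes would share 978 genes that rose and then fell and 1043 that fell and then rose. They would also share 977 that rose in both comparisons and 1043 that fell in both, where 377 and 558 were found. The GM-CSF libraries enter both comparisons with opposite sign, so chance alone gives a negative correlation across genes. Pearson's r across the 12340 genes was -0.40, and 20 simulations with no effect gave a mean of -0.50, from -0.53 to -0.44. Spearman's rho was -0.46 against a simulated -0.45. Genes are not independent replicates. Neither coefficient was beyond the simulations in the direction of opposition. With noise alone, however, the shared libraries set both coefficients whatever the size of the noise. Coefficients from noise are no benchmark where real changes are large, so this comparison does not decide whether the opposite changes arose by chance. The covariance was -0.259, against a simulated mean of -0.0232 with a lowest value of -0.0266. The simulations held noise only, of the size seen between replicates. The covariance lay beyond all 20 of them, which argues against replicate noise in the shared libraries as the whole cause of the opposite changes. A difference common to both GM-CSF libraries is not covered by the simulations, and how DON acted was not tested.

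The third comparison, GM-CSF with DON against no GM-CSF, does not use the means of the libraries with GM-CSF alone. Those libraries still entered the filter, the scaling and the shared estimate of spread. Ccl17 (10.79 ± 0.09), Car4 (10.41 ± 0.10), Ear6 (7.74 ± 0.15), Cish (6.45 ± 0.12) and Nov (5.84 ± 0.11) were the most raised genes with a mean of at least 10 CPM. Fyb (-6.68 ± 0.24), Irg1 (-5.98 ± 0.17), Treml4 (-5.48 ± 0.14), Cd300lh (-5.27 ± 0.19) and Mmp14 (-5.19 ± 0.14) were the most lowered. The fold change of Fyb ranged from -7.96 without DON replicate 1 to -5.94 without DON replicate 2. Ear11 was at least 128-fold higher than the floor of the group without GM-CSF. The adjusted p of these 10 genes lay between 1.07e-12 and 1.18e-08.

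In edgeR's test 6859 genes differed between cells with GM-CSF and DON and cells with neither, 3353 higher and 3506 lower, of which 1427 differed by at least 2-fold (631 and 796). Of the 623 genes that GM-CSF had raised at least 2-fold, 411 (66.0%) were still higher with DON than without GM-CSF, 165 (26.5%) did not pass and 47 were lower. Of the 823 lowered at least 2-fold, 610 (74.1%) were still lower, 180 (21.9%) did not pass and 33 were higher. The median log2 fold changes of these sets were 1.57 and -1.49 with GM-CSF and 1.14 and -1.11 with GM-CSF and DON. Both contrasts share the libraries without GM-CSF. In 20 simulations that kept this sharing and gave the DON libraries the means without GM-CSF, the 2-fold genes had median log2 fold changes with DON of 0.02 and -0.02 on average. A further 2263 genes changed with DON but did not pass with GM-CSF, 1301 up and 962 down, of which 237 and 129 by at least 2-fold.

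Relative to no GM-CSF, 36 of 39 genes of the ATF4 amino acid response were higher with DON and 1 was lower, also adjusted over the list alone, with a median of 1.21 (2.31-fold). Asns was up by 2.13 ± 0.07. The camera test gave adjusted p = 2.26e-16, and adjusted p = 0.464 with an estimated correlation. Of 25 unfolded protein response genes, 21 were higher and 0 lower, also adjusted over the list alone, with camera adjusted p = 4.95e-10 and adjusted p = 0.464 with an estimated correlation. Of 63 genes of the TCA cycle and oxidative phosphorylation, 31 were higher and 6 lower, also adjusted over the list alone, with camera adjusted p = 0.00209 and adjusted p = 0.602 with an estimated correlation. The mitochondrially encoded share was 3.21% without GM-CSF and 2.54% with GM-CSF and DON.

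Cholesterol synthesis was the most lowered of the camera calls, with 22 of 25 genes lower and 0 higher, also adjusted over the list alone, and a median of -1.57 (2.96-fold lower). In the camera test the adjusted p was 3.24e-11, and 0.464 with an estimated correlation. Of 25 NRF2 and oxidative stress genes, 21 were lower and 3 higher, also adjusted over the list alone (camera adjusted p = 4.79e-07, and adjusted p = 0.464 with an estimated correlation). Of 40 DNA replication and G1/S genes, 28 were lower and 5 higher, also adjusted over the list alone (camera adjusted p = 3.34e-05, and adjusted p = 0.507 with an estimated correlation). Of 20 genes of fatty acid synthesis and LXR targets, 14 were lower and 3 higher, also adjusted over the list alone (camera adjusted p = 0.00209, and adjusted p = 0.473 with an estimated correlation). Of 21 interstitial and monocyte-derived macrophage markers, 14 were lower and 4 higher, and 15 and 4 adjusted over the list alone (camera adjusted p = 0.00258, and adjusted p = 0.464 with an estimated correlation). Of 25 NF-kB inflammatory genes, 14 were lower and 6 higher, and 16 and 6 adjusted over the list alone (camera adjusted p = 0.0188, and adjusted p = 0.464 with an estimated correlation). Of 24 glycolysis genes, 12 were lower and 4 higher, also adjusted over the list alone (camera adjusted p = 0.0278, and adjusted p = 0.473 with an estimated correlation).

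The other 17 lists did not pass, with camera adjusted p between 0.0503 and 0.746. Of the 40 mitosis genes, 5 were higher, 19 lower and 16 did not pass, with a median of -0.24 and adjusted p = 0.0675. Mki67 differed by -0.25 ± 0.18 (adjusted p = 0.267), but by -0.50 without no GM-CSF replicate 2 (adjusted p = 0.00560). Myc was lower (-0.44 ± 0.06). Pparg differed by 0.06 ± 0.05, Siglec5 by -0.06 ± 0.05, Csf2ra by 0.09 ± 0.04 and Csf2rb by 0.03 ± 0.04, and none of these 4 passed edgeR's test, with adjusted p between 0.0772 and 0.559. Under upper quartile scaling Csf2ra passed (0.13, adjusted p = 0.0177).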

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

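The crossed replicate block, in which the replicate numbers of the group without GM-CSF were exchanged, was chosen only after the data were seen, and all other alternatives were set before the data were examined. In edgeR, DESeq2 and limma the number of genes changed stayed within 1.5 times its main value in each comparison, except with a minimum fold change of 2. That threshold left 1446, 1156 and 1427 genes for GM-CSF against none, DON against GM-CSF and GM-CSF with DON against none, because smaller changes no longer counted. The share of GM-CSF-responsive genes that changed in the opposite direction with DON was then 29.1%, against 55.8% without it. Under the other alternatives with all replicates the counts were from 5545 to 7220, from 5674 to 7308 and from 5381 to 7063, and the share was from 51.6% to 56.9%. Leaving out 1 library at a time gave from 5686 to 6893, from 5884 to 7304 and from 5723 to 6570 genes, and a share from 50.7% to 58.8%. A group left with 1 library was assumed to vary like the others. Upper quartile scaling changed the split of genes up and down most, to 3077 and 3882, 4268 and 2970, and 3798 and 3136. The median log2 fold change of all genes was then -0.05, 0.08 and 0.05, against -0.02, 0.01 and 0.01 with the main scaling.

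With the replicate number as a block, 6708, 6882 and 6542 genes changed, the share was 55.6%, and 15, 15 and 10 lists passed. The crossed block gave 7220, 7303 and 7063 genes. The labels do not pair the replicates. Differences between replicates correlated across genes at -0.048 between no GM-CSF and GM-CSF and at 0.068 between GM-CSF and GM-CSF with DON. Between no GM-CSF and GM-CSF with DON the value was -0.311. Equal numbers thus did not act as a pairing, but a factor shared in crossed order by the last 2 groups is not excluded.

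Of 27 lists, 15, 15 and 10 passed camera in the 3 comparisons. With an estimated correlation, which has 3 degrees of freedom, camera passed 0, 0 and 0 lists, with 4, 2 and 2 at an unadjusted p under 0.05, so the list calls rest on the preset correlation of 0.01. With the estimated correlation, the adjusted p with GM-CSF against none was 0.361 for G1/S and immediate early, 0.285 for mitosis, ATF4, glutamine, purine and pyrimidine, fatty acid oxidation, interferon, MYC, NRF2, unfolded protein, interstitial and dendritic cells, 0.312 for TCA cycle and 0.322 for cholesterol. For DON against GM-CSF it was 0.453 for alveolar macrophage identity, 0.312 for STAT5 targets, G1/S, mitosis, purine and pyrimidine, glycolysis, NF-kB, interferon, immediate early, MYC and alternative activation, 0.547 for ATF4 and cholesterol and 0.473 for TCA cycle and fatty acid synthesis. For GM-CSF and DON against none it was 0.507 for G1/S, 0.464 for ATF4, cholesterol, NF-kB, NRF2, unfolded protein and interstitial, 0.473 for glycolysis and fatty acid synthesis and 0.602 for TCA cycle.

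Directional fry passed 24, 21 and 24 lists and mixed fry 27, 25 and 27. Fry does not compare a list with other genes, so its calls answer another question than those of camera. Why more lists passed was not tested. For lists that camera did not pass, the adjusted p of directional fry with GM-CSF against none was 0.00129 for alveolar macrophage identity and STAT5 targets, 0.0223 for glycolysis, 0.0161 for NF-kB and alternative activation and 0.0183 for MHC class II and lymphocytes. It was 0.00115 for granulocytes and mast cells and 0.0138 for stroma and endothelium. For DON against GM-CSF it was 0.00443 for glutamine, 0.0116 for fatty acid oxidation, p53 and lung epithelium, 0.00752 for interstitial and 0.00782 for granulocytes and mast cells. For GM-CSF and DON against none it was 0.000825 for alveolar macrophage identity, 0.0189 for STAT5 targets, 0.00813 for glutamine and p53 and 0.0126 for purine and pyrimidine. It was 0.00199 for fatty acid oxidation, 0.0307 for immediate early, 0.0188 for MHC class II, alternative activation and lung epithelium and 0.0157 for lymphocytes. It was 0.000979 for granulocytes and mast cells, 0.0149 for stroma and endothelium and 0.00258 for dendritic cells.

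The adjusted p of mixed fry for such lists with GM-CSF against none was 1.22e-07 for alveolar macrophage identity, 8.39e-06 for STAT5 targets, NF-kB and MHC class II, 1.43e-05 for glycolysis and 0.000147 for fatty acid synthesis. It was 3.05e-05 for p53, 2.49e-06 for alternative activation, 0.000256 for lung epithelium and 0.00642 for lymphocytes. It was 8.93e-05 for granulocytes and mast cells and 0.00682 for stroma and endothelium. For DON against GM-CSF it was 4.68e-05 for glutamine, 3.76e-05 for fatty acid oxidation, 5.51e-05 for MHC class II, p53 and NRF2 and 4.43e-05 for unfolded protein. It was 0.000116 for interstitial, 0.000128 for lung epithelium, 0.000132 for granulocytes and mast cells and 0.00190 for dendritic cells. For GM-CSF and DON against none it was 5.14e-06 for alveolar macrophage identity and STAT5 targets, 0.000407 for mitosis, 0.000124 for glutamine and 5.49e-05 for purine and pyrimidine. It was 6.15e-05 for fatty acid oxidation, 0.000229 for interferon and MYC, 1.60e-05 for immediate early and alternative activation and 0.000246 for MHC class II. It was 6.69e-05 for p53, 0.00560 for lung epithelium, 0.00157 for lymphocytes and 8.18e-05 for granulocytes and mast cells. It was 0.000280 for stroma and endothelium and 1.82e-05 for dendritic cells. With DESeq2 size factors 15, 15 and 13 lists passed, and the 3 added in the third comparison were 0.0494 for alveolar macrophage identity and 0.0497 for purine and pyrimidine and fatty acid oxidation.

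Of 281 gene results named, 5008 alternatives gave 4877 on the same side of the threshold. Another 124 no longer passed, 90 of these from the minimum fold change of 2, and 7 newly passed. A change of direction was counted only where the gene was called in the main fit or the alternative, and 0 were found. Genes called in neither could change direction, such as Cd4 with DON, with 1 count in both groups compared. Its log2 fold change was 0.05, and -0.89 without GM-CSF replicate 1. Counts limited the genes near 0, and a floor or a ratio with a counting interval is given for some of them. Fitted log2 fold changes printed for such genes, among them Nos2, Cd4 and Scgb1a1, are no bounds.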

Other observations

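The test of how many lysosomal genes shared the change was chosen only after the result was seen, and so were the values of Ogt, Mgea5, Txnip, Nos2, Ctsd, Mcoln1, Phgdh and Shmt2 given here; the tests of GC content, outlying libraries and scaling were set before their results were seen.

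The mitosis genes were higher with GM-CSF and lower with DON, and 3 technical explanations were tested. After removal of a trend with GC content and transcript length, which explained little of the fold changes over all genes (r squared 0.00965 and 0.00568), the list medians were 1.23 with GM-CSF and -1.45 with DON, against 1.26 and -1.45 before. Without either GM-CSF library, at least 40 and 39 of the 40 members stayed called in the same direction. Under the other scalings the medians nearest 0 were 1.23 and -1.37. These values argue against a GC or length trend, a single outlying GM-CSF library or the scaling as the whole cause. An effect of the culture conditions on division remains a candidate explanation that was not tested, and counts of cells were not used here.

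Of 25 cholesterol synthesis genes, 22 were lower and 1 higher with GM-CSF, and 18 were lower and 1 higher with DON than with GM-CSF alone. The medians were -1.09 and -0.42 after the GC and length correction, 20 of 22 and 17 of 18 members stayed called without either GM-CSF library, and the medians nearest 0 under other scalings were -1.14 and -0.32. The same technical explanations are therefore argued against as the whole cause. No biological explanation was tested.

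A further pattern concerned the lysosome. Ctsd was at 20248 ± 115, 10357 ± 147 and 14986 ± 521 CPM without GM-CSF, with GM-CSF and with DON, and Mcoln1 at 117 ± 0.529, 83.5 ± 0.700 and 194 ± 2.45 CPM. A list of 48 lysosomal genes was then written from general knowledge without the genes whose values had been seen, and Gaa was left out after a first run that had included it. Of the 48, 33 fell and 8 rose with GM-CSF (median -0.28), 32 rose and 6 fell with DON (median 0.23), and 17 were higher and 18 lower with DON than without GM-CSF (median 0.02). Both changes were found in 24 (50.0%), while 10000 random lists matched on expression had a median of 10, a 95th percentile of 14 and a highest value of 21. The count was in line with a change shared by many lysosomal genes, though genes are not independent of each other. With GM-CSF the median was -0.28 after the GC and length correction, and 32 of 33 members stayed called without either GM-CSF library, which argues against those causes. With DON 27 of 32 stayed called, and the corrected median was 0.24 with a bootstrap interval from 0.111 to 0.348. That interval reached below the bound set in advance, so the test did not decide on a GC or length trend in the rise with DON. The interval measures the spread among members, and the correction itself did not lower the median. Scaling was not tested for the lysosomal genes. Upper quartile scaling moved the median log2 fold change of all genes with DON from 0.01 to 0.08.

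Ogt, the O-GlcNAc transferase, was at 87.0 ± 8.09, 56.5 ± 3.40 and 130 ± 9.41 CPM (log2 fold changes -0.62 ± 0.08 with GM-CSF and 1.20 ± 0.08 with DON). Mgea5, the O-GlcNAc hydrolase, was at 67.7 ± 2.24, 71.4 ± 2.27 and 21.5 ± 3.16 CPM, did not pass with GM-CSF (adjusted p = 0.423) and fell with DON (-1.73 ± 0.08, adjusted p = 1.97e-07). Txnip was at 245 ± 4.84, 137 ± 3.69 and 57.9 ± 2.36 CPM. Nos2 had 1 count without GM-CSF, 1 with GM-CSF and 136 with DON, a ratio of 142 between the last 2 groups with a counting interval from 25.1 to 5650. The fitted log2 fold change, which is no bound, was 6.83, and 9.12 and 6.06 without GM-CSF replicate 1 and 2. Within the ATF4 list, Phgdh (-0.25 ± 0.05), Shmt2 (-0.45 ± 0.05) and Psat1 (-0.88 ± 0.05) fell with DON while Ddit3, Trib3, Chac1 and Sesn2 rose. No explanation of these values was tested.

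The gene length implied by counts and FPKM was compared between groups with limma, to see whether differences in it follow the groups. Of 8365 genes with at least 200 counts in each library, 0 changed in each comparison, and 631, 763 and 726 had an unadjusted p under 0.05, where 418 would by chance. The number changed was also 0 with a non-robust fit. Small differences that follow the groups are therefore not excluded.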
